A study of Mus musculus with 4 samples.

How the data were processed

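LSK cells were sorted from fetal livers of wild-type and Brpf1-null mouse embryos at E14.5. Per the labels' protocols, cells from 4 embryos were pooled per sample, total RNA was isolated from about 10000 cells, and oligo-dT-primed libraries were sequenced on an Illumina HiSeq instrument. The samples form 2 pairs of a wild-type and a Brpf1-null sample, and pair 1 was loaded on 2 lanes and pair 2 on 6 lanes, per the labels' protocols. Samples were assigned to groups from their genotype labels.

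Reads were aligned with TopHat to the mm9 mouse genome, per the submitters' processing notes. The TopHat version, the gene annotation, the program that counted reads and any filter are not given in the sources used here. The authors deposited 1 table per pair with a value per gene and library: RPKM in the table of pair 1 and FPKM in the table of pair 2, per the file headers, which both scale reads by gene length and by library size. Each table also held the authors' fold change, a ratio of wild-type to Brpf1-null values, per the file headers and the values. It also held the log2 of that ratio, as deposited. All 12624 deposited fold changes equalled the wild-type value divided by the Brpf1-null value within 0.001, and the other 7583 genes had no fold change because 1 or both values were 0. The deposited fold changes therefore run opposite to the direction used here, in which a positive log2 change means higher in the Brpf1-null library. They were not used further.

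The 2 tables were compared before any other step. All 20207 gene symbols matched, and 0 wild-type values, 0 Brpf1-null values and 0 fold changes differed. Because the 2 tables carry the same values under different unit names, they were read as 1 library per genotype, and the values are called RPKM here. Values of a second library per genotype were not analysed here. The design fixed before the data were examined planned a limma test with the pair as a block, gene set tests with camera and fry, and the correlation of fold changes between pairs, and it stated that with 1 library per group no test would be made and values would be described. That rule was followed for genes and lists. The later tests of explanations compare values with set bounds and give no p-values.

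Changes were computed as log2((Brpf1-null RPKM + 1)/(wild-type RPKM + 1)), which understates the change of low genes. Folds in the text are ratios of RPKM without a pseudocount, and counts of genes past 1.5-fold use the log2 change with the pseudocount. Genes were kept with a mean of at least 1 RPKM over the 2 libraries, which left 9380 genes and removed 10827. Listed zeros occurred in both libraries for 5979 genes, in wild-type alone for 645 and in Brpf1-null alone for 959. They include genes with near-identical copies, so a 0 is given only as a listed value.

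Library sizes were recovered from the spacing of low values, since in RPKM 1 read is worth an amount set by gene length and library size. Symbols were matched to GENCODE M21 transcript lengths, directly for 17518 genes and through RefSeq synonyms for 2302 (98.1% in all). That annotation is of the GRCm38 assembly, not mm9, so it was used for names, lengths and GC content, and coordinates are not given. The recovered sizes were 23655652 reads for wild-type and 22227251 for Brpf1-null. With them, 51.3% of 1573 values of genes with a single transcript length came out as whole reads within 0.1 read, against 24.2% with sizes raised by 5%. Independent of length, 42.1% of 1203 genes under 0.3 RPKM had a ratio of whole reads up to 6 within 0.2%, against 2.5% with the library ratio raised by 5%. Read numbers were then estimated per gene, as whole reads where a transcript length gave them in both libraries (3349 genes) and otherwise from the median transcript length, so they are approximate. The 95% counting interval of a fold is the exact Clopper-Pearson interval of the Brpf1-null share of a gene's reads, scaled by the library sizes. Genes without a matched length have no interval. The wild-type library had 13583 genes above 0 and 10.4% of its summed RPKM in its top 10 genes, and the Brpf1-null library 13269 and 9.08%.

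The genes named were chosen by a rule fixed before the data were examined: Brpf1, the 12 highest and 12 lowest log2 changes among genes with at least 5 RPKM in the higher library, up to 4 measured members per gene list with the largest absolute log2 change, and the sex-linked genes. Genes named outside that rule are marked as such, and some genes that the rule takes are not reported here. The 29 gene lists were also fixed before the data were examined and cover stem cell regulators, blood lineages, hepatocytes, endothelial and stromal cells, cell cycle, stress and housekeeping groups, and Brpf1's partners and neighbours. A list with at least 3 measured genes was placed by its median log2 change among 10000 random lists of the same size drawn from 20 expression bins, as a description of these 2 libraries. The interval of a list's median is the 95% binomial interval from order statistics over genes, which are not replicates.

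Alternatives fixed before the data were examined were a pseudocount of 0.1 or 5, no filter beyond a value above 0, a mean of at least 5 RPKM, centring of each library on its median, quantile normalization and a 2-fold threshold. A GC correction was added after seeing the data: a polynomial trend of degree 3 of the log2 change on the GC content of each gene's longest transcript was subtracted for the 9258 kept genes (98.7%) with a GC value. After it the Spearman rho with GC content across genes was 0.001.

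The steps were tested on simulated data. From simulated reads on 19820 genes, both library sizes were recovered within 0.001%, with the same lengths that were used to simulate the reads. Of 5 simulated lists per size, all 5 lay outside the central 95% at log2 changes of 1, −1, 2 and −2, and 1 of 100 unchanged lists did, over 9257 genes. The simulated genes varied independently and their changes were larger than most list medians here. These rates therefore do not carry over to lists of genes that vary together or to smaller changes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.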

Results

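LSK cells, the lineage-negative, Sca-1-positive, Kit-positive fraction that holds the hematopoietic stem cells and multipotent progenitors, were sorted from the livers of wild-type and Brpf1-null mouse embryos at E14.5, and their RNA was sequenced from oligo-dT-primed libraries. Brpf1 encodes a chromatin reader that joins MYST-family histone acetyltransferases to ING and MEAF6 proteins. The labels describe 2 samples per genotype, each a pool of about 10000 cells from 4 embryos, arranged as 2 pairs. The tables of the 2 pairs held identical values for all 20207 genes, in the wild-type column and in the Brpf1-null column. They were counted as 1 library per genotype (n = 1). The sources used here do not give which pair the values belong to, or whether they merge reads of both pairs. The wild-type library held about 23655652 reads and the Brpf1-null library about 22227251, as read from the spacing of the low RPKM values. No difference between the libraries has a replicate check, so p-values were not computed. The range in brackets after a fold is its 95% counting interval. It covers counting error only, and not the spread between embryos or pools. It also treats reads as independent, which PCR copies of a molecule are not, so it can be too narrow.

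The comparison asks which transcripts differed between fetal liver stem and progenitor cells labelled Brpf1-null and wild-type. Brpf1 itself was at 2.59 RPKM in the wild-type library and 2.15 RPKM in the Brpf1-null library, 1.20-fold lower (1.0 to 1.44), from about 271 and 212 reads. A value over the whole gene does not resolve a deleted part of the transcript, so it is a weak check of the labels. Loss of Brpf1 in the sorted cells was not shown by these values. Among the 10 measured genes for subunits of BRPF1 complexes and their paralogs, 9 lay within 1.5-fold with the pseudocount. Phf15 (Jade2, a scaffold of HBO1 acetyltransferase complexes) was 2.15-fold higher (1.71 to 2.72) in the Brpf1-null library. Kat5, which encodes the acetyltransferase TIP60, was at 6.06 and 9.45 RPKM, 1.56-fold higher (1.275 to 1.928) without the pseudocount. Myst2 (HBO1) was at 12.7 and 14.2 RPKM. The median log2 change of this list was 0.08, and −0.03 after each library was centred on its median. The 10 measured neighbours of Brpf1 on its chromosome had a median log2 change of 0.30, a value that 710 of 10000 random lists matched on expression reached; with a pseudocount of 5 (percentile 97.9) and with no filter (97.6) it lay above the central 95%. Of these neighbours, Creld1 was 1.98-fold higher (1.37 to 2.87) and Arpc4, a subunit of the actin-nucleating Arp2/3 complex, 1.49-fold higher (1.42 to 1.57).

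Transcripts of B-lineage, erythroid, megakaryocyte and liver cells were among the lowest in the Brpf1-null library relative to wild-type, and stem cell regulators such as Hoxa9, Mecom and Meis1 were lower as well. The medians of the monocyte, interferon and antigen-presentation lists were higher, with most interferon and antigen-presentation members within 1.5-fold. Of the 9380 genes with a mean of at least 1 RPKM, 1323 were at least 1.5-fold higher and 884 at least 1.5-fold lower in the Brpf1-null library, and 7173 (76.5%) lay within 1.5-fold. Over the 9258 kept genes with a read estimate, the counting interval excluded 1 for 1310 of the higher and 867 of the lower genes. The rest of the genes past 1.5-fold had an interval that included 1 or had no interval. Higher genes made up 59.9% of those past 1.5-fold with the values as deposited, but 44.4% (961 higher, 1204 lower) after centring each library on its median, which shifted the median change of all genes from 0.04 to −0.07 on the log2 scale, a shift of −0.11. The split was 52.3% (1132 higher, 1033 lower) after quantile normalization and 58.7% after removal of a trend on GC content. That trend was a feature of these libraries: the log2 change correlated with the GC content of the transcript across genes (Spearman rho = 0.289 over 9258 genes, which are not independent replicates), and its median ran from −0.16 in the lowest GC decile to 0.26 in the highest. Across genes, expression in the 2 libraries had a Pearson r of 0.955 on the log2 scale.

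**Figure D1:**
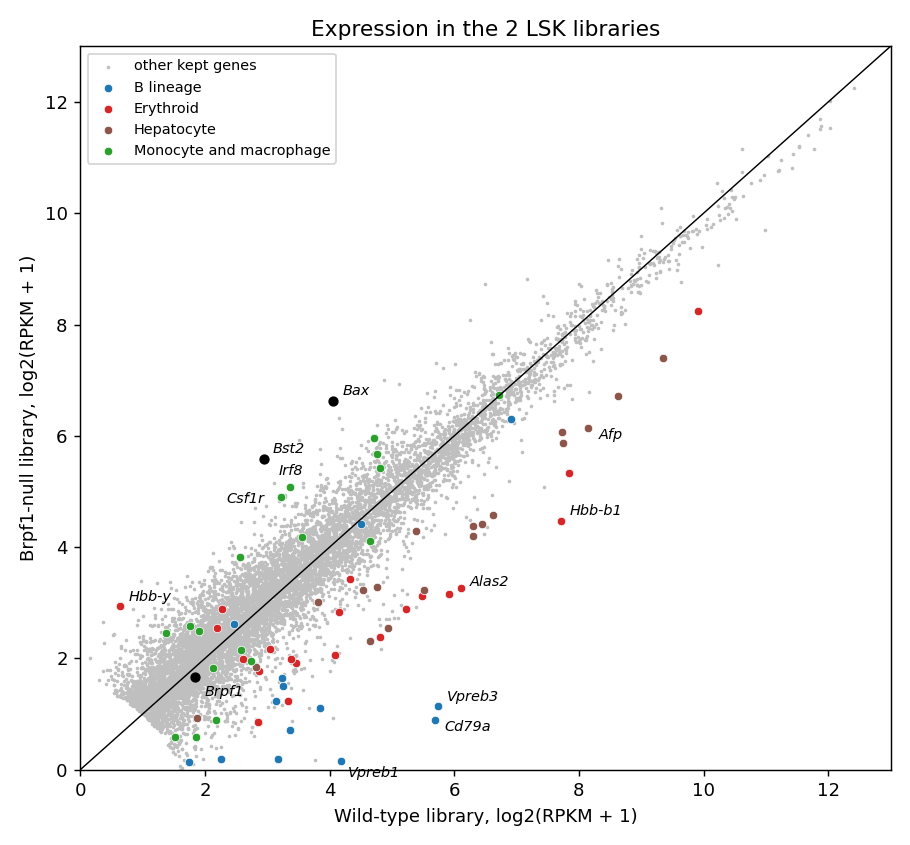
Expression of 9380 genes in the wild-type library (x axis) and the Brpf1-null library (y axis), both as log2(RPKM + 1), with 1 point per gene, the line of equal expression, and B-lineage, erythroid, hepatocyte and monocyte or macrophage genes in colour. Cd79a (50.6 and 0.848 RPKM) lies far below the line with most other B-lineage genes, the hepatocyte genes form a band below it, and Bst2 (6.68 and 47.1 RPKM) and Bax (15.7 and 98.0 RPKM) lie above it.

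Among genes with at least 5 RPKM in the higher library, the 12 with the lowest log2 change included 6 genes of B-cell development, among them Cd79a, Vpreb1, Vpreb2, Vpreb3 and Ebf1, and 3 erythroid genes, among them Hbb-b1 and Alas2. The other 3 were Ppbp (a platelet chemokine), Darc (the Duffy chemokine receptor, 17.6-fold lower, 11.6 to 28.7) and Serpina1e (a liver alpha-1-antitrypsin, 7.77-fold lower, 6.37 to 9.52). The 12 with the highest log2 change were led by Bst2 (tetherin, an interferon-induced membrane protein), which was at 6.68 RPKM in the wild-type and 47.1 RPKM in the Brpf1-null library, 7.05-fold higher (5.68 to 8.85). Bax, a pro-apoptotic BCL2-family member, was at 15.7 and 98.0 RPKM, 6.26-fold higher (5.47 to 7.18). Aldh2, a mitochondrial aldehyde dehydrogenase, was 6.22-fold higher (5.30 to 7.32), Hcls1, a hematopoietic cortactin homolog, 5.74-fold (4.99 to 6.64) and Qsox1, a sulfhydryl oxidase, 9.79-fold (7.48 to 13.1). Arpc1b, a subunit of the Arp2/3 complex, was at 89.5 RPKM in the wild-type and 424 RPKM in the Brpf1-null library, and the adhesion protein gene Parvg was 4.68-fold higher (3.92 to 5.62). The others were Hbb-y, an embryonic beta-like globin, at 12.2-fold (6.09 to 29.8, from about 8 and 94 reads), Glp1 at 17.9-fold (7.18 to 55.2, from about 5 and 82 reads), Rcc1 at 5.45-fold, Robld3 (Lamtor2) at 4.49-fold and the chemokine gene Ccl5 at 6.83-fold (4.23 to 11.8). After the GC trend was removed, the log2 changes of these 12 genes ran from 1.94 to 2.49.

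Genes of stem cell multipotency and self-renewal were lower as a group in the Brpf1-null library. Of 37 measured members, 10 were at least 1.5-fold lower, 2 were at least 1.5-fold higher and 25 lay within 1.5-fold. Hoxa9, a homeobox regulator of stem cell expansion, was at 8.37 RPKM in the wild-type library and 1.23 RPKM in the Brpf1-null library, 6.82-fold lower (4.45 to 11.2). Its cofactor Meis1 was at 44.2 and 17.0 RPKM, 2.60-fold lower (2.43 to 2.78). Mecom, which encodes the stem cell factor EVI1, was 4.14-fold lower (1.87 to 10.3), and Myct1 3.77-fold lower (3.14 to 4.57). The list's median log2 change was −0.33 (−0.54 to −0.10, binomial interval of the median over genes), and 0 of 10000 random lists matched on expression had a median as low. The 4 genes whose products mark or refine the LSK gate were chosen after their values were seen. Kit was 1.20-fold lower (1.10 to 1.31) and Ly6a, which encodes Sca-1, 1.11-fold lower (0.801 to 1.55), a difference not detectable at this depth. Cd34 was 1.54-fold higher (1.49 to 1.58) and Flt3 1.45-fold higher (1.37 to 1.53). In the same libraries the hepatocyte genes were 3.84-fold lower at the median and the Y-linked gene Ddx3y was 3.56-fold lower.

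**Figure D2:**
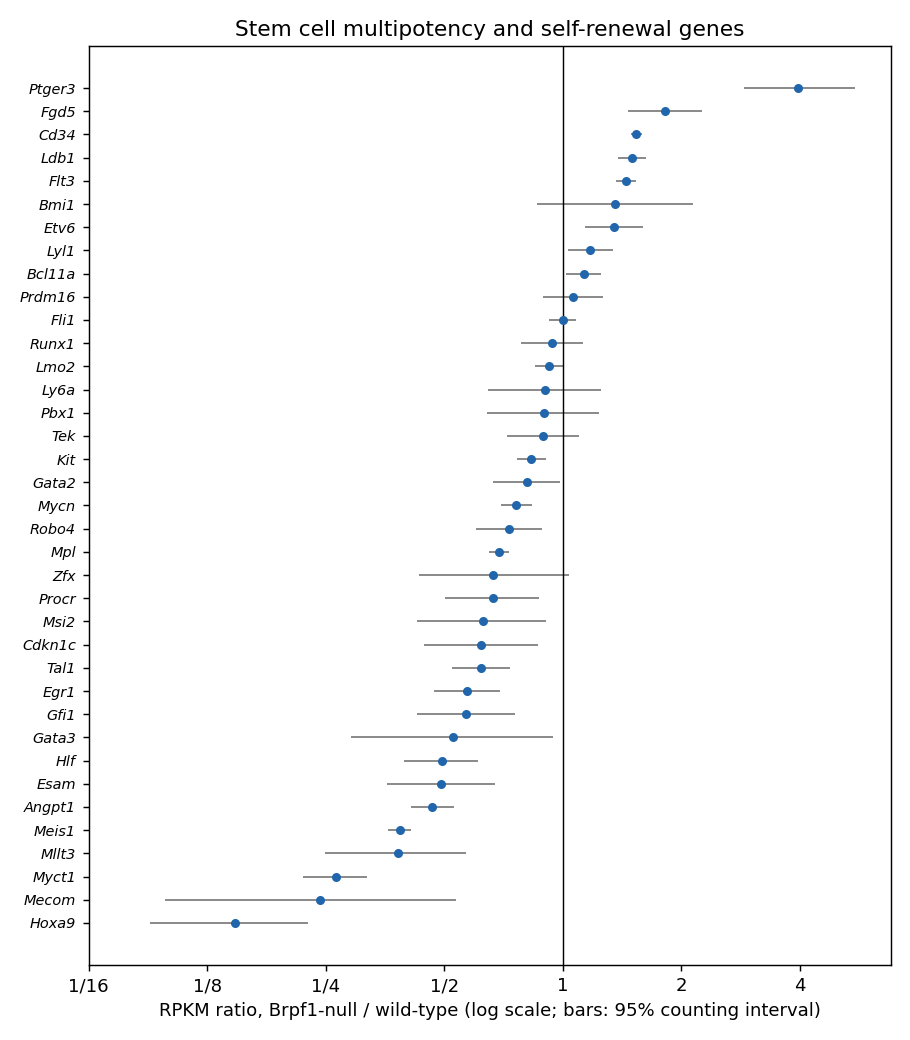
RPKM ratio of the Brpf1-null to the wild-type library for 37 stem cell multipotency and self-renewal genes on a log axis, where each point is 1 gene, each bar its 95% counting interval and the vertical line equal expression. Hoxa9 (6.82-fold lower), Mecom (4.14-fold lower) and Myct1 (3.77-fold lower) lie farthest to the left, and Ptger3 (3.96-fold higher) farthest to the right.

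Within the HoxA cluster, 4 genes were measured. Hoxa10 was 2.62-fold lower (1.66 to 4.22) and Hoxa5 1.90-fold lower (1.30 to 2.82) beside Hoxa9, while Hoxa7 was at 9.01 and 9.16 RPKM, a log2 change of 0.02 that turned to −0.09 after centring, −0.06 after quantile normalization and −0.07 after removal of the GC trend. The cluster's median of −0.65 was matched by 94 of 10000 random lists, and it was −0.04 when genes under 1 RPKM were kept, where the percentile was 40.5, and at percentile 2.5 with a pseudocount of 5. No gene of the HoxB cluster passed the filter (0 of 10). The 7 measured fetal stem cell genes had a median log2 change of 0.17, which 3244 random lists reached. They went both ways: Arid3a, a B-lineage and fetal stem cell factor, was 3.65-fold higher (3.09 to 4.34) and Igf2bp1 1.75-fold higher (1.34 to 2.27), while the RNA-binding protein gene Igf2bp2 was 1.97-fold lower (1.5 to 2.61).

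B-lineage transcripts were lower in the Brpf1-null library. Of 14 measured genes of B cells and common lymphoid progenitors, 12 were at least 1.5-fold lower in the Brpf1-null library and 0 were higher by that much. Cd79a, which encodes the signalling chain of the B-cell receptor, was at 50.6 RPKM in the wild-type library and 0.848 RPKM in the Brpf1-null library, 59.7-fold lower (41.6 to 92.3). The surrogate light chain genes Vpreb1 and Vpreb3 were 145-fold (30.9 to 936, on about 2 Brpf1-null reads) and 43.9-fold lower (27.6 to 74.4). The B-cell specification factor Ebf1 was 11.7-fold lower (9.18 to 15.01) and Vpreb2 14.9-fold lower (7.82 to 29.3). The median gene was 13.2-fold lower, and 0 of 10000 random lists had a log2 median as low as −1.99. The 2 members within 1.5-fold were Ikzf1 and Satb1, which earlier progenitors also express (named after their values were seen). Pax5 was listed at 0 in both libraries. The hepatocyte genes, at a median of 3.84-fold, were lower in the same library. Of the 7 measured T and NK cell genes, 4 were higher and 0 lower by 1.5-fold. Cd4 was 4.24-fold higher (2.61 to 6.90) and Id2, an inhibitor of E proteins, 2.06-fold higher (1.94 to 2.20). Their median log2 change of 0.59 was reached by 98 of 10000 random lists, and the list lay inside the central 95% of random lists with no filter (percentile 89.4) and with a mean of at least 5 RPKM (97.47).

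Erythroid and megakaryocyte transcripts were lower, and so were those of hepatocytes, a cell type outside the LSK definition. Of 21 measured erythroid genes, 18 were at least 1.5-fold lower and 2 at least 1.5-fold higher, with a median fold of 3.64 lower. Alas2, the erythroid enzyme that starts heme synthesis, was at 67.7 and 8.62 RPKM, 7.86-fold lower (6.85 to 9.02). The blood group gene Rhd was 5.76-fold lower (5.38 to 6.17). The adult beta-globin gene Hbb-b1 was at 208 and 21.3 RPKM, with no counting interval because its transcript length was not matched, and it shares sequence with Hbb-b2. The 3 erythroid genes that were higher were the embryonic globins Hbb-y (12.2-fold) and Hba-x (1.68-fold, 1.21 to 2.35), and Tspan33. Hba-x and Tspan33 were named after their values were seen. The near-identical alpha-globin copies Hba-a1 and Hba-a2 were listed at 0 in both libraries and are not read as absent. Of 9 measured megakaryocyte genes, 5 were lower and 0 higher by 1.5-fold. Ppbp was 101-fold lower (34.3 to 493, on about 3 Brpf1-null reads), Pf4, another platelet chemokine, 5.42-fold lower (4.03 to 7.51) and Clec1b 6.14-fold lower (3.22 to 13.7). The megakaryocyte median of −0.82 was below all 10000 random lists, but with a mean of at least 5 RPKM it was −0.31, at percentile 7.79.

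Hepatocyte genes were lower in all 18 measured members by at least 1.5-fold. The most abundant, Apoa2, was at 654 RPKM in the wild-type library and 168 RPKM in the Brpf1-null library, and the fetal liver protein gene Afp at 283 and 69.1 RPKM (both named after their values were seen). Serpina1a was 6.09-fold lower (5.13 to 7.33), Apoh 6.10-fold (4.53 to 8.51) and the fibrinogen gene Fgg 5.34-fold (4.75 to 6.04). The list's summed RPKM was 2304 in the wild-type and 608 in the Brpf1-null library. The median log2 changes of the hepatocyte list (−1.92) and the erythroid list (−1.68) lay below those of all 10000 random lists. Endothelial genes had a median of −0.24 over 10 members, which 329 random lists matched; it passed below the central 95% with no filter (percentile 0.04) and after removal of the GC trend (0.28). Emcn, an endothelial sialomucin, was 2.33-fold lower (2.0 to 2.72) and the receptor gene Tie1 1.62-fold higher (1.45 to 1.81). Of the 6 measured mast cell, basophil and eosinophil genes, 2 were lower and 2 higher by 1.5-fold, and the median was −0.19 (percentile 12.02). Prg2, the eosinophil major basic protein gene, was 2.72-fold lower (2.21 to 3.35) and the basophil protease gene Prss34 5.46-fold higher (3.17 to 9.99). The stromal list had 2 measured members, Dlk1 (2.69-fold lower, 1.98 to 3.70) and Postn (2.30 and 1.81 RPKM), too few to place against random lists.

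Myeloid transcripts went both ways. Of 18 measured monocyte and macrophage genes, 10 were higher and 4 lower by 1.5-fold. Irf8, a transcription factor of monocyte and dendritic cell progenitors, was at 9.24 RPKM in the wild-type and 32.6 RPKM in the Brpf1-null library, 3.53-fold higher (3.08 to 4.04). Csf1r, the receptor for the macrophage growth factor CSF1, was 3.47-fold higher (3.03 to 3.99). The macrophage genes Vcam1 and Timd4 were 4.11-fold (3.09 to 5.62) and 5.25-fold lower (3.38 to 8.48). The median log2 change of 0.61 was reached by 1 of 10000 random lists, though with no filter it was 0.11, at percentile 80.8. Among 17 neutrophil and granulocyte progenitor genes, 3 were higher and 7 lower by 1.5-fold. Cebpa, a granulocyte and monocyte specification factor, was 3.64-fold higher (2.90 to 4.59), and Mpo, a primary granule enzyme, was at 351 and 570 RPKM (named after its value was seen). S100a8 was 3.54-fold lower (3.07 to 4.12), Ngp 3.03-fold (2.60 to 3.57) and Lcn2 5.89-fold (3.15 to 12.5). The median of this list was 0.38 and its mean −0.23, so the signs differed, and the median turned to −0.23 with no filter. It was at percentile 99.4 of its random lists, but at 93.3 with a pseudocount of 5, at 77.2 with a mean of at least 5 RPKM and at 0.77 with no filter.

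Interferon-response genes were higher in 7 and lower in 1 of 24 measured members by 1.5-fold, with a median log2 change of 0.39 that 10 of 10000 random lists reached. Beside Bst2, Mx1 was 3.61-fold higher (1.37 to 10.8), Isg15 2.23-fold (1.53 to 3.30) and Irf7 1.92-fold (1.45 to 2.53). Of 12 genes of MHC class II and antigen presentation, 3 were higher and 0 lower by 1.5-fold. The class II chain gene H2-Aa was 3.01-fold higher (2.08 to 4.56), the peptide transporter gene Tap1 2.53-fold (2.17 to 2.96) and the invariant chain gene Cd74 1.86-fold (1.68 to 2.07). Their median of 0.35 was reached by 128 random lists, and it lay inside the central 95% with no filter (percentile 93.6), with a mean of at least 5 RPKM (94.9) and after removal of the GC trend (93.8). Immediate early genes had a median of 0.22 over 18 members, which 957 random lists reached, and with no filter it was at percentile 98.8. Of these, Myc was at 55.4 and 92.8 RPKM and Fos at 25.3 and 42.4 RPKM.

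The mitosis and proliferation list lay below the central 95% of its random lists, and the DNA replication list inside it. Of 26 mitotic genes, 6 were lower, 2 higher and 18 within 1.5-fold, with a median of −0.25 (−0.49 to 0.03, an interval over genes that includes 0) that 35 of 10000 random lists matched. Ube2c, which loads ubiquitin for the anaphase-promoting complex, was 3.30-fold lower (3.06 to 3.57), Nusap1, a spindle protein gene, 3.28-fold (2.87 to 3.76) and Prc1 2.43-fold (2.15 to 2.75), while the checkpoint kinase gene Bub1b was 2.18-fold higher (1.77 to 2.69). Of 28 DNA replication genes, 3 were lower and 3 higher by 1.5-fold. Their median was −0.07 (−0.22 to 0.18) and their mean 0.01, and 2958 random lists had a median as low. The intervals of the mitotic and replication medians overlap, and the difference between these lists was not tested. Rrm2, a ribonucleotide reductase subunit, was at 230 and 119 RPKM, and Chaf1a, a histone chaperone gene, at 9.84 and 19.98 RPKM. Of 19 replication-dependent histone genes, 11 were lower and 1 was higher by 1.5-fold, with a median of −0.63 that 0 random lists matched. Hist1h2bj was 3.17-fold lower (2.11 to 4.77) and Hist2h4 5.13-fold higher (3.24 to 9.0). Most replication-dependent histone transcripts lack a poly(A) tail and their genes are near-identical copies, so these values are uncertain in an oligo-dT library.

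Of 19 measured p53 targets, 5 were higher and 2 lower by 1.5-fold, with a median of 0.13 that 3493 random lists reached and that turned to −0.14 with no filter. Bax was the highest of them, Ak1 was 2.48-fold higher (2.0 to 3.09), and Plk2 and Sesn1 were 3.14-fold (2.41 to 4.12) and 1.91-fold lower (1.78 to 2.05). With the pseudocount, all 8 measured inhibitors of cyclin-dependent kinases and senescence genes lay within 1.5-fold. Their median of −0.39 was matched by 106 random lists, and it was at percentile 7.09 with a mean of at least 5 RPKM. Without the pseudocount, Cdkn1c (p57), Cdkn2d and Cdkn1b were 1.61-fold, 1.51-fold and 1.56-fold lower. Cdkn1c was at 6.40 and 3.98 RPKM and Trp53 at 195 and 148 RPKM. Antioxidant defence genes were lower in 9 and higher in 0 of 21 members by 1.5-fold, with a median of −0.49 that 0 random lists matched, in the libraries where the erythroid and hepatocyte medians were 3.64-fold and 3.84-fold lower. Nqo1, a quinone reductase gene, was 8.83-fold lower (4.60 to 19.02), Foxo1 3.01-fold (2.56 to 3.55), Gclc, which makes the glutathione precursor, 2.13-fold (1.59 to 2.91) and the erythroid-rich peroxiredoxin gene Prdx2 1.84-fold (1.80 to 1.88).

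Imprinted genes were lower in 7 and higher in 0 of 14 measured members by 1.5-fold, with a median log2 change of −0.61 that 0 of 10000 random lists matched. That median was −0.34 with no filter and −0.33 with a pseudocount of 5, and the hepatocyte genes were 3.84-fold lower at the median in the same libraries. The noncoding RNA gene Meg3 was 3.45-fold lower (2.0 to 6.55), Ndn (necdin) 2.39-fold (2.11 to 2.71) and Grb10, a growth factor receptor adaptor, 2.28-fold (1.70 to 3.11), beside Dlk1, which hepatoblasts also express. Cytosolic ribosomal protein genes had a median of −0.25 over 77 members, of which 5 were lower and 0 higher by 1.5-fold. Only 1 random list was as low, yet after quantile normalization the median was −0.05, at percentile 8.32. Rpl13 was at 1202 and 538 RPKM and Rpl37a at 1463 and 955 RPKM, and ribosomal protein genes share reads with many processed pseudogenes. Oxidative phosphorylation genes split evenly, with 5 of 76 higher and 5 lower by 1.5-fold, and their median of −0.06 (percentile 52.3) turned to 0.01 after quantile normalization. Cox7a1 was 2.57-fold higher (1.64 to 4.11) and Ndufs5 2.23-fold lower (1.42 to 3.75). In all, 26 of the 29 lists had at least 3 measured members, and 5 lay above and 12 below the central 95% of their random lists.

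**Figure D3:**
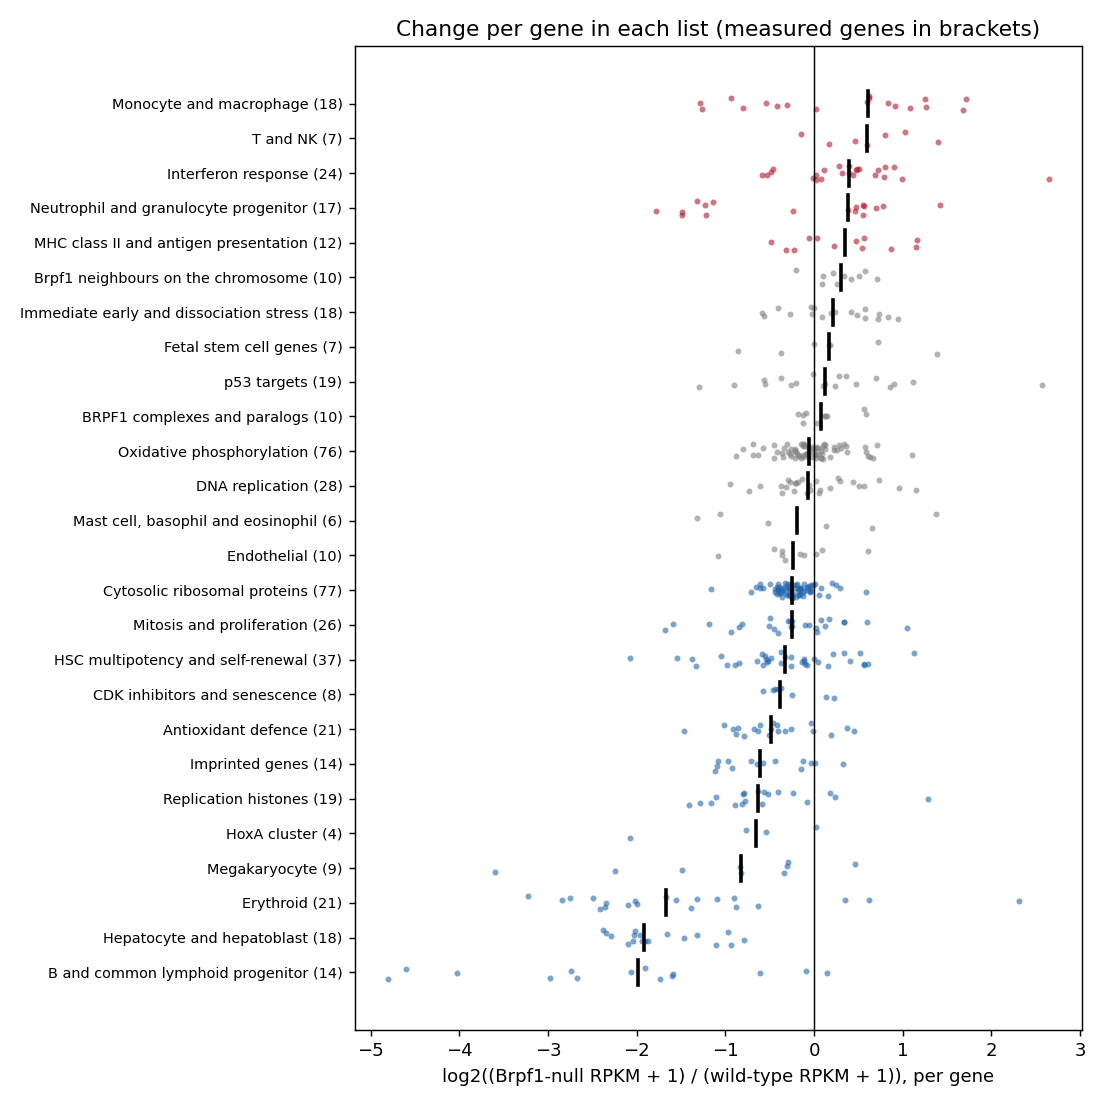
Log2 change of each measured gene, Brpf1-null over wild-type with 1 RPKM added to both, in 26 gene lists, where each point is 1 gene and each black bar the list's median, and colour marks lists above (red) or below (blue) the central 95% of random lists matched on expression. B-lineage (−1.99), hepatocyte (−1.92) and erythroid (−1.68) medians are the lowest, and the monocyte and macrophage median (0.61) is the highest.

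The 2 libraries also differed in transcripts of the sex chromosomes. The Y-linked genes Ddx3y and Eif2s3y were 3.56-fold (2.88 to 4.42) and 2.88-fold lower (2.17 to 3.82) in the Brpf1-null library. Kdm5d was 2.02-fold lower (1.44 to 2.90) and Uty 5.15-fold lower (1.44 to 26.8, on about 3 Brpf1-null reads), both under the filter. Xist, the noncoding RNA of the inactive X chromosome, was also under the filter, at 0.319 and 0.781 RPKM, 2.45-fold higher (1.84 to 3.26). The sex of the pooled embryos is not given in the sources used here.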

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

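The GC correction was chosen after the data were seen, and the other settings before. No paired analysis was possible because both pairs' tables hold the same values, which leaves 1 library per genotype. For the same reason the fits without the replicate block, without the intensity trend, without each library or pair and with an adjusted p of 0.1, the estimated inter-gene correlation and the correlation between pairs were not run. For 122 named genes, 793 alternative values were set against the reported log2 change, with the width of the counting interval placed around that change. Of these, 671 stayed within that width, and 122 moved beyond it or had no interval. The printed intervals are of folds without a pseudocount, and some of the 671 lie outside them. With a pseudocount of 5, Clec1b was at −0.58 and was counted as within, against a printed interval of 3.22 to 13.7-fold lower. The sign turned for Hoxa7 (centring, quantile normalization and GC correction) and Postn (GC correction, 0.02), both with counting intervals that include 1. Genes past 1.5-fold numbered 1323 higher and 884 lower, against 554 and 393 with a pseudocount of 5, which shrinks low genes by construction, 793 and 483 with a mean of at least 5 RPKM, where 5546 genes remain, and 388 and 325 at 2-fold. Of the 17 lists past either end, 17 stayed past it with a pseudocount of 0.1 and with centring, 16 with quantile normalization and with GC correction, 15 with a pseudocount of 5, 12 with no filter and 11 of the 16 still measured with a mean of at least 5 RPKM. The lists above the central 95% went from 5 to 3 with no filter, of which only the interferon list was among the 5, and to 2 (monocyte and interferon) with a mean of at least 5 RPKM. The ribosomal median of −0.25 was −0.36 with centring, −0.052 with quantile normalization and −0.29 with GC correction. With no filter the neutrophil median reversed from 0.38 to −0.23 and the replication histone median moved from −0.63 to −0.19. Apart from the pseudocount, filter and threshold effects named, the cause was not tested. Depth limits the lowest genes, such as Vpreb1 and Ppbp with about 2 and 3 Brpf1-null reads.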

Other observations

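The hepatocyte-share, erythroid-range, B-lineage-range and single-pool tests were chosen only after the results they weigh were seen. The GC tests rest on a correction added after the list medians were seen, with their bounds set before the corrected values were seen. The Xist test was set before the Xist value was seen, but after the Y-linked values.

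Some stem cell transcripts under the filter were also lower in the Brpf1-null library, with counting intervals that exclude equal expression. Slamf1, which encodes the stem cell marker CD150, was at 0.566 RPKM in the wild-type library and 0.0335 RPKM in the Brpf1-null library, 16.9-fold lower (4.35 to 145, on about 36 and 2 reads). Trpc6, a cation channel gene, was at 0.999 and 0.069 RPKM, with an interval of 5.94 to 45.8 for its fold lower. Within the HoxA cluster, Hoxa4 went the other way, at 0.332 and 1.21 RPKM, 3.64-fold higher (1.86 to 7.13). Hmox1, the inducible heme oxygenase gene, was at 1.15 RPKM in the wild-type library and listed at 0 in the Brpf1-null library. These genes were chosen after their values were seen.

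Hepatocyte, erythroid and B-lineage transcripts were lower in the Brpf1-null library. Removing the GC trend left the hepatocyte median log2 change at −1.94 and the B-lineage median at −1.87. Medians of the GC deciles ran only from −0.16 to 0.26, so a trend of that size was too small to account for either. With the pseudocount, the medians before removal of the trend were −1.92 for hepatocyte and −1.99 for B-lineage genes. The ratios that follow have no pseudocount. On that scale the 14 measured B-lineage genes had a median log2 ratio of −3.72. That lies below the lowest hepatocyte gene (−2.61, SD of the hepatocyte genes 0.48). Of the 14, 8 lay below every hepatocyte gene, lower than a source with the hepatocyte ratios alone would give. Another 3, Cd79b, Ikzf1 and Satb1 (named after their values were seen), lay above the hepatocyte range. The comparison weighs only a shared ratio. It cannot exclude a source whose B-lineage share differed between the libraries, or one behind part of the fall. A candidate explanation for the hepatocyte part is more carried-over liver RNA in the wild-type library, which an LSK gate would normally exclude. Of the 18 measured hepatocyte genes, among them Apoa2 (654 and 168 RPKM) and Afp (283 and 69.1 RPKM), 94.4% lay within 2-fold of their median ratio. Whether the erythroid part shares that source stays open, since 52.4% of the 21 measured erythroid genes lay within the hepatocyte range (−2.61 to −0.88), 6 below it and 4 above it, of which 3 (Hbb-y, Hba-x and Tspan33) were higher in the Brpf1-null library. An effect of the genotype on these cells, B-lineage cells in the wild-type pool or pools, which the lineage-negative gate would normally remove, and a difference between pools stay open and untested.

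The Y-linked genes were lower in the Brpf1-null library, and Xist, which was under the filter, was 2.45-fold higher (1.84 to 3.26). Both fit a smaller share of male embryos among those pooled for the Brpf1-null library. That is a hypothesis that the data could have excluded and did not. The share of each sex in the pools was not measured, and an effect of genotype on these genes stays open.

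The stem cell multipotency list was lower in the Brpf1-null library. Hoxa9, Myct1 and Mecom had the lowest log2 changes, with the pseudocount, among its members past the filter. The list's median log2 change was −0.36 after removal of the GC trend against −0.33 before. Its genes had a median GC content of 49.5%, in a decile with a median log2 change of 0.05. Removal could therefore shift the list's median little, and the values say only that the fitted trend did not account for it. With values for 1 library per genotype, a genotype effect and a difference between pools that is not tied to genotype cannot be told apart. A second library per group would be needed to see the spread.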
